A study of Homo sapiens with 6 samples.

How the data were processed

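Polyadenylated RNA of HPNE-hTERT cells was sequenced after 4 days of FOLFIRINOX or vehicle, 3 libraries per group. Per the labels' protocols, mRNA was enriched with an NEB kit and libraries were made with the KAPA RNA HyperPrep kit. Per the submitters' processing notes, the authors used FastQC 0.12.1, STAR 2.7.11b, featureCounts 2.0.6 and DESeq2 with GRCh38. The annotation release, the strand setting, the DESeq2 version and its design are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

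The deposited table holds, for 62754 genes, a library-size-normalized signal per library, the authors' log2 fold changes with standard errors, a Wald statistic or score, and p-values. Every normalized value was a whole multiple, within 0.001, of the value of 1 read in its column (100% of values), so the read count of each gene in each library was recovered by the authors' size factors. The baseMean signal equalled the mean of the 6 columns, and the deposited score equalled log2 fold change over its standard error. DESeq2 1.42.0 rerun on the recovered reads with treatment as the only term gave the authors' standard errors with a median absolute difference of 8.9e-09, and the same counts of calls, 2208 higher and 2300 lower. With P number added, 3372 were higher and 3446 lower. Even values made up 72.3% to 74.8% of the recovered counts below 50 in each library, as when both ends of a fragment are counted. Counting intervals here treat each read as independent, so they are too narrow if that is so, and they cover counting error only.

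The gene name column of the deposited table gave symbols for 42523 of the 62754 genes, and Ensembl identifiers were kept for the rest. GENCODE 29 gave gene coordinates, exonic lengths and GC content. The 6 columns carry the treatment and a P number (P14, P15 or P19) that appears in no label, so columns were assigned to groups and not to numbered samples. The planned block on the labels' replicate numbers was therefore replaced by a block on P number, chosen after seeing the data. To see whether P numbers pair libraries, deviations from group means were correlated over the 17951 tested genes. Libraries with the same P number correlated at 0.257, 0.282 and 0.288, all above the 0.1 set for pairing, and libraries with different P numbers at −0.26 to −0.03. The P numbers were thus read as pairs from the column names. No label says that libraries came from separate cultures, so p-values measure only the spread between these libraries. Replicates differed by more than sampling noise, with chi-square per degree of freedom from 75.3 to 236.

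Tests, lists, named genes and alternatives were fixed before the data were examined unless said otherwise. The main test was limma 3.58.1 with a mean-variance trend on log2(value + 1), for genes with a value of 10 or more in at least 3 libraries, with Benjamini-Hochberg adjustment at 0.05. Folds on this scale understate the change of low genes. The median standard error of a log2 difference was 0.226, a 95% half-width of 0.497. An exact permutation test of 3 against 3 cannot give a p below 0.1. Gene lists (22 pathway lists and 6 cell type lists, written from general knowledge) were tested with camera at a preset correlation of 0.01 when 5 or more members were measured, adjusted over 24 lists. Camera was repeated with an estimated correlation, and fry was run as a test of each list alone. The repeat rests on the few residual degrees of freedom of the libraries, so a list that fails it is not shown to be unchanged. Named genes were 25 fixed genes, the 8 largest rises and 8 largest falls among called genes with non-overlapping groups and a mean of 100 or more in the higher group, and up to 2 members per direction and list with a mean of 50 or more. A count of 0 was given a floor of 3 reads per library. Some genes that this rule names are not reported here.

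Alternatives were pseudocounts of 0.5 and 8, no filter, a filter at 50, TMM, common-total and quantile scaling, limma without trend, edgeR 4.0.16 quasi-likelihood and DESeq2 on the recovered reads, and leaving out each library. On the recovered reads edgeR called 1987 genes higher and 2183 lower. Chosen after seeing the data were the P number block, leaving out both P14 libraries because their mitochondrial ribosomal RNA share was the highest of each group, edgeR on reads divided by 2, removal of each library's GC trend, and that removal with the block. GC content was known for 96.5% of tested genes. In simulated data with 200 changed genes the limma step, run on 17102 genes, recovered 2 of 67 genes changed 1.5-fold, 33 of 67 changed 2-fold and 64 of 66 changed 4-fold, with 5 false calls, and called 0 of 20 unchanged lists. Far fewer genes changed there than were called in the data, so the adjusted threshold was stricter and the recovered shares may be too low. Simulated genes were drawn independently and without pairs, so the unchanged lists do not test camera under correlation between genes. Analyses used Python 3.11.15 and R 4.3.3.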

Results

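The data were RNA sequencing of HPNE-hTERT cells, a non-malignant human pancreatic ductal epithelial line immortalized with telomerase. Cells received the chemotherapy mixture FOLFIRINOX for 4 days (oxaliplatin at 5 µM, SN-38 at 25 nM and 5-fluorouracil at 10 µM) or the vehicle DMSO, with 3 libraries per group. SN-38 is the active form of the topoisomerase I inhibitor irinotecan. Per the labels, the treatment was given to induce senescence, and the series concerns mitochondrial iron and ferroptosis in senescent cells. The comparison therefore asks which RNAs, among them those of iron handling and of ferroptosis, an iron-dependent death by lipid peroxidation, differ after the drugs. Gene counts summed to 86421747, 83981154 and 91992824 reads in the FOLFIRINOX libraries P14, P15 and P19, and to 92355768, 86435436 and 97762802 in the vehicle libraries of the same names. Values below are normalized reads, given as mean ± SD with n = 3 per group, and folds are on the log2(value + 1) scale.

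FOLFIRINOX-treated cells had far less RNA of cell division genes and more RNA of p53 target genes than vehicle cells. MKI67, the Ki-67 proliferation antigen, fell from 13874 ± 3569 to 30.2 ± 6.65 normalized reads (log2 difference −8.78 ± 0.24 SE, limma adjusted p = 3.4e-09). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 22156 ± 4997 to 203806 ± 27900.2 (3.22 ± 0.19, adjusted p = 7.4e-07), a 9.30-fold difference. LMNB1, the nuclear lamina gene lamin B1, fell 47.7-fold, from 6094 ± 1120 to 125 ± 8.46 (adjusted p = 1.1e-08). Of 17951 genes tested, 2047 were higher and 2191 lower in FOLFIRINOX at adjusted p under 0.05 in the unpaired limma fit. Of these, 1212 and 1046 differed at least 2-fold. With libraries paired by P number, 3995 were higher and 3918 lower. Groups did not overlap for 39.5% of all genes tested, where chance gives 10%.

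**Figure D1:**
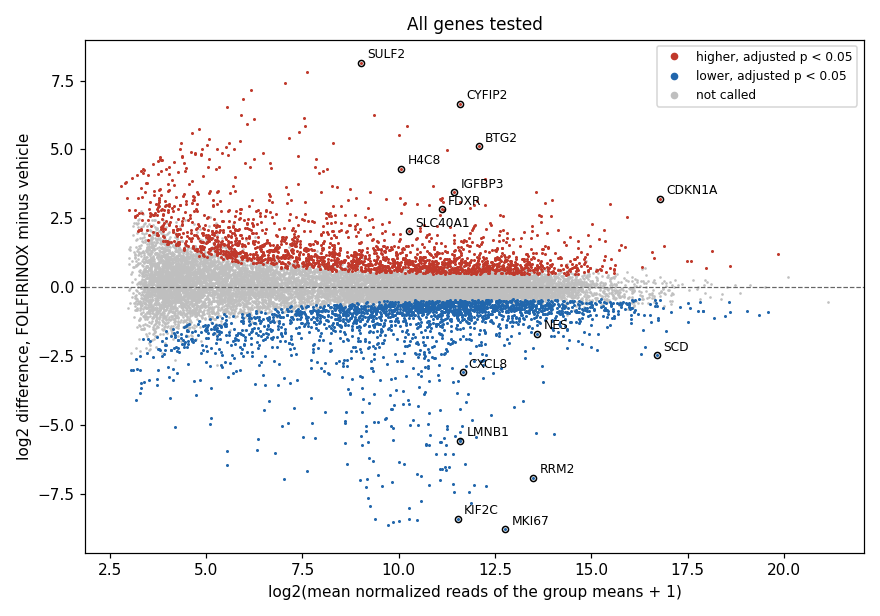
Log2 difference between FOLFIRINOX and vehicle (vertical axis) against the log2 mean level in normalized reads (horizontal axis) for the 17951 genes tested, 3 libraries per group. Red points are the 2047 genes called higher by the unpaired limma fit, blue points the 2191 called lower and gray points genes not called. Circled genes are named in the text.

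The largest rises among called genes with a mean of 100 or more in the higher group included SULF2 and CYFIP2. SULF2, a heparan sulfate 6-O-endosulfatase, rose from 2.7 ± 1.2 to 1042 ± 318 normalized reads. CYFIP2, an actin regulator, rose from 62.8 ± 24.5 to 6153 ± 774 (log2 difference 6.65 ± 0.26, limma adjusted p = 3.0e-08). CLCA2 rose from 19.7 ± 16.8 to 1281 ± 270.0, and PINCR, a long noncoding RNA induced by p53, from 1.37 ± 2.37 to 391 ± 89.3. CYP3A7 and DSG3 had no read in any vehicle library and means of 141 ± 10.8 and 121 ± 55.1 in FOLFIRINOX, at least 46.8-fold and at least 40.1-fold higher against a floor of 3 reads per vehicle library. CYP3A7 has near-identical paralogs that can share its reads. CES3 and PLEKHG1 had 2 reads each over the vehicle libraries against 799 and 360 in FOLFIRINOX, ratios of 390.2 (95% counting interval 108 to 3228) and 176 (48.3 to 1457). Below MKI67, the largest falls were all in cell division and chromatin assembly genes. ERCC6L fell from 1680.0 ± 490.2 to 3.27 ± 1.15, AURKB from 1850.2 ± 119 to 4.55 ± 2.99, NEK2 from 2046 ± 658 to 4.55 ± 0.916, and UBE2C from 2835 ± 337 to 7.17 ± 0.887. The log2 differences of SPC25, ASF1B and KIF2C were −8.41, −8.40 and −8.39.

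All 30 p53 target genes on a list fixed beforehand rose, with a median log2 difference of 2.16 (camera adjusted p = 2.0e-24, and adjusted p = 0.0575 with an estimated correlation between genes). BTG2, an antiproliferative gene, rose 34.5-fold to 8364 ± 1813, and GDF15, a stress-induced secreted factor, 8.16-fold to 2550.3 ± 425. All 29 measured mitosis genes fell (median −6.43, adjusted p = 3.5e-35, and adjusted p = 0.0575 with an estimated correlation). Of 33 DNA replication genes 30 fell (median −2.37, adjusted p = 5.8e-25, and adjusted p = 0.0575 with an estimated correlation), led by RRM2 and MCM10 at −6.91 and −6.40. PCNA, a replication clamp gene that p53 also activates, was the only member called higher, from 15831 ± 2451 to 32392 ± 2895. Of 24 homologous recombination and Fanconi genes 19 fell and none was called higher (median −2.83, adjusted p = 2.7e-13, and adjusted p = 0.122 with an estimated correlation), with RAD54L and FANCA lowest at −6.42 and −4.90. With pairing by P number (replicate block), 2 recombination genes were called higher and 20 lower.

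Replication-dependent histone genes, whose mRNAs normally end without a poly(A) tail, went the other way from the replication genes. Of 17 measured, 13 rose and none was called lower (median 2.21, adjusted p = 2.8e-09, and adjusted p = 0.254 with an estimated correlation). H4C8 rose from 102 ± 14.7 to 2043 ± 455 (4.29 ± 0.22) and H2BC5 from 278 ± 110 to 3533 ± 1424 (3.67 ± 0.32). Histone genes are a multigene family of similar sequences, so their counts are uncertain. Beside this group, the mitochondrial ribosomal RNA share of reads was 2.74%, 1.18% and 1.23% in the FOLFIRINOX libraries P14, P15 and P19, against 0.864%, 0.563% and 0.552% in vehicle. Without both P14 libraries, 12 histone genes were called higher.

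Of the fixed senescence markers, CDKN2A, the p16 and p14ARF locus, was 398 ± 61.1 in FOLFIRINOX and 561 ± 109 in vehicle (−0.49 ± 0.21, adjusted p = 0.121), and with the replicate block its adjusted p was 0.0165. CDKN2B rose slightly, from 2101 ± 232 to 2989 ± 18.2 (0.51 ± 0.16, adjusted p = 0.0353). Its call was lost when any of FOLFIRINOX P14, P15 or P19 or vehicle P14 or P19 was left out (adjusted p 0.0755 to 0.123). Of 31 measured senescence-associated secretory genes 7 rose and 15 fell (median −0.83, adjusted p = 0.0094, and adjusted p = 0.325 with an estimated correlation). CXCL8, the chemokine IL-8, fell from 5746 ± 2646 to 720.3 ± 462 (−3.08 ± 0.40, adjusted p = 2.9e-04), IL6 from 249 ± 56.9 to 91.8 ± 25.8 (−1.44 ± 0.28, adjusted p = 0.0038) and CXCL5 from 1884 ± 94.7 to 367 ± 64.0. IGFBP3, a binding protein of insulin-like growth factors, rose from 484 ± 181 to 5091 ± 1161, and the epidermal growth factor receptor ligand AREG from 828 ± 274 to 2809 ± 804. Of 25 interferon-stimulated genes 2 rose and 4 fell (adjusted p = 0.609), and with the replicate block 4 rose and 7 fell. The falling members numbered 2 when FOLFIRINOX P19 or vehicle P14 was left out, and without both P14 libraries 1 rose and 2 fell. The list's median was 0.01, its mean −0.16 and its camera direction down.

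**Figure D2:**
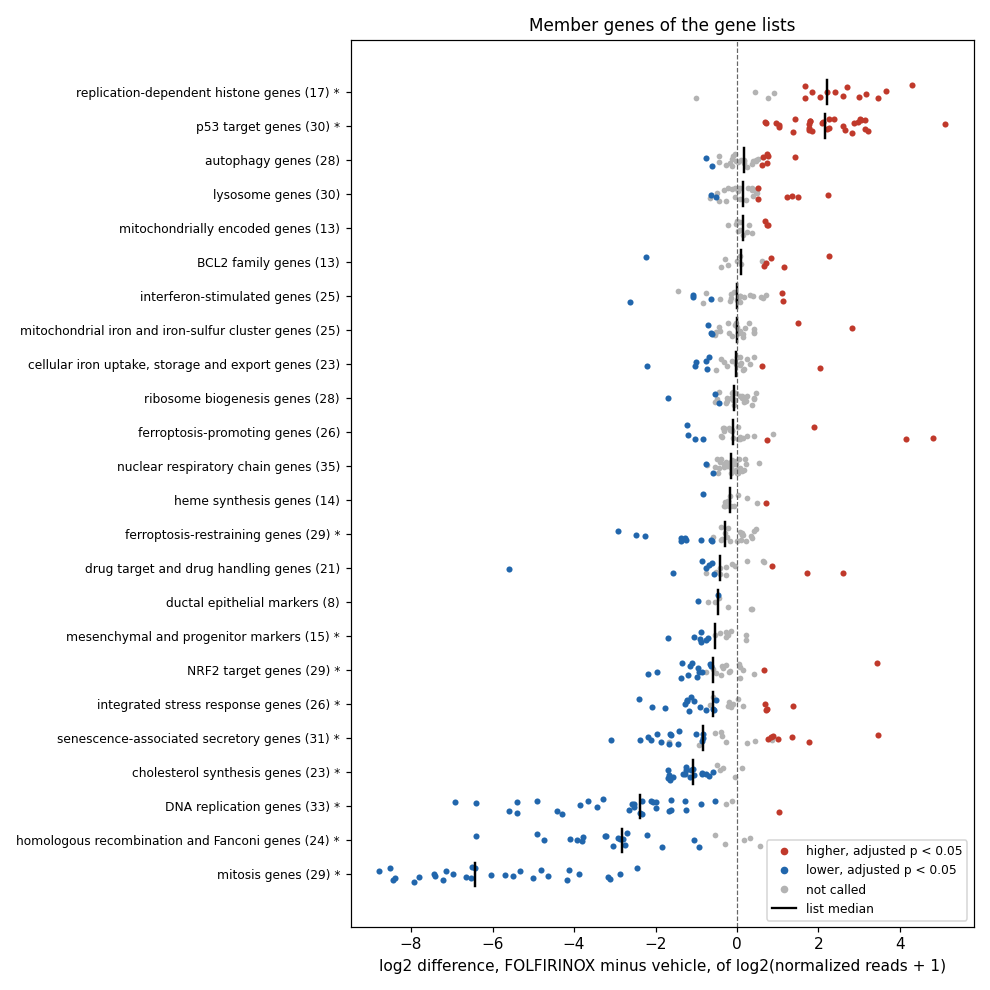
Log2 difference between FOLFIRINOX and vehicle (horizontal axis) for the member genes of 24 gene lists, 1 point per gene, with the number of measured members in brackets. Red and blue points passed adjusted p under 0.05 in the unpaired limma fit, and black bars are list medians. Asterisks mark the 11 lists past the threshold with a preset correlation, none of which passed with an estimated correlation.

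Among genes of cellular iron handling, SLC40A1, the iron exporter ferroportin, rose 4.07-fold, from 489 ± 50.1 to 1990 ± 182 (2.02 ± 0.17, adjusted p = 1.1e-05). The zinc and iron importers SLC39A14 and SLC39A8 fell, from 16530.0 ± 1708 to 8127 ± 705 and from 1722 ± 230.3 to 846 ± 48.4. The ferrireductase CYBRD1 rose 1.53-fold, and its call was lost without FOLFIRINOX P19 (adjusted p = 0.0822), vehicle P14 (0.0522) or vehicle P15 (0.0513). The transferrin receptor TFRC was 15895 ± 412 in FOLFIRINOX and 15299 ± 3390.1 in vehicle (0.08 ± 0.18, 95% interval −0.31 to 0.47, adjusted p = 0.782). The ferritin subunits FTH1 and FTL differed by 0.08 ± 0.18 and 0.16 ± 0.26, and NCOA4, the receptor that delivers ferritin to lysosomes, by 0.25 ± 0.16 (adjusted p = 0.775, 0.702 and 0.282), and FTL had an adjusted p of 0.0165 with the replicate block and GC trends removed. HMOX1, the heme-degrading oxygenase, differed by −0.40 ± 0.21 (adjusted p = 0.199, and 0.0398 with the replicate block). Over the whole list of 23 measured genes 2 rose and 6 fell, with a median of −0.02 and adjusted p = 0.312. Only 1 rose when FOLFIRINOX P19, vehicle P14, vehicle P15 or both P14 libraries were left out.

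**Figure D3:**
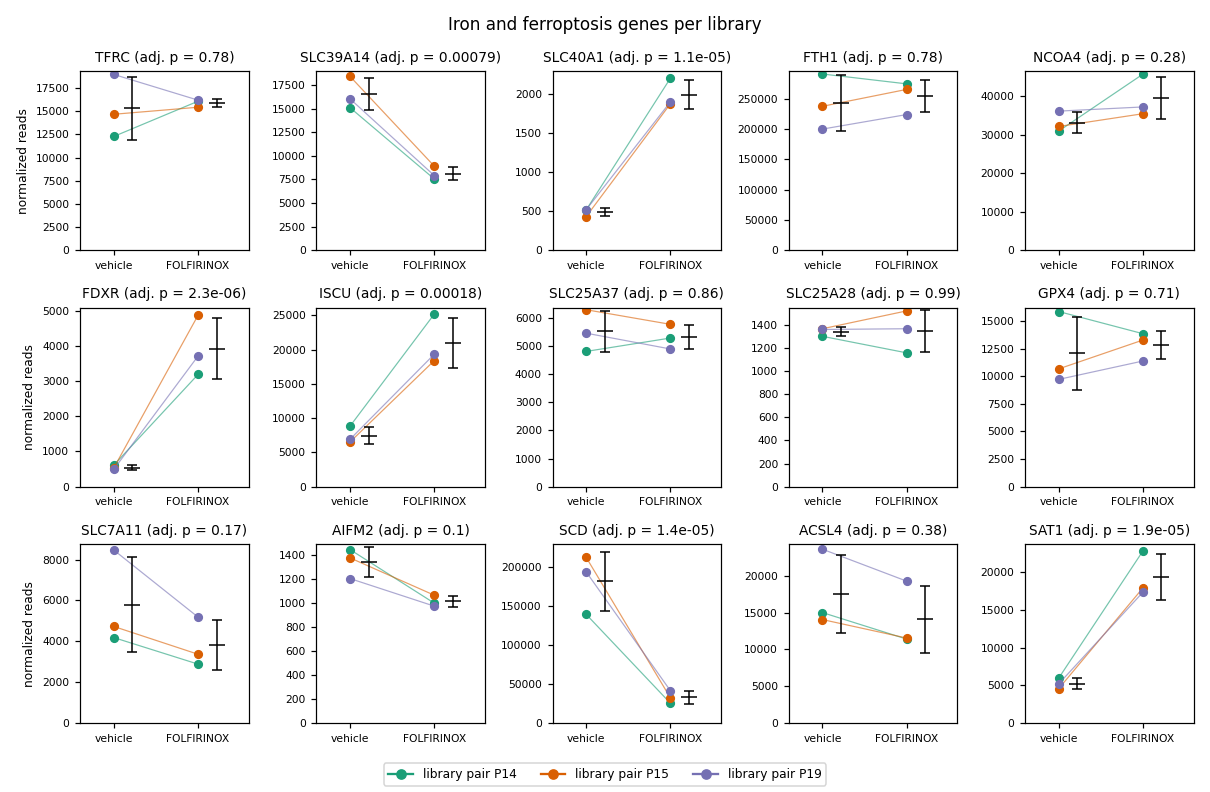
Normalized reads per library (vertical axis, from 0) of 15 iron and ferroptosis genes in vehicle and FOLFIRINOX. Colored points are single libraries, lines join libraries with the same P number, and black bars show mean ± SD with n = 3. Panel titles give the adjusted p of the unpaired limma fit, which does not use the P number. SLC40A1, FDXR, ISCU and SAT1 lie higher and SLC39A14, SCD and AIFM2 lower in every FOLFIRINOX library than in any vehicle library. AIFM2 was not called.

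In the mitochondrial iron and iron-sulfur cluster list, FDXR, a ferredoxin reductase that is also on the p53 list, rose from 545 ± 60.3 to 3922 ± 860.0 (2.83 ± 0.19, adjusted p = 2.3e-06). ISCU, the scaffold on which iron-sulfur clusters are built, rose from 7417 ± 1235 to 20967 ± 3678 (2.82-fold, adjusted p = 1.8e-04). The mitochondrial iron importers SLC25A37 and SLC25A28 differed by −0.05 ± 0.16 (95% interval −0.40 to 0.31) and 0.00 ± 0.17 (−0.37 to 0.37). FTMT, mitochondrial ferritin, had 0 reads in every library, below a floor of 3 reads per library, and was not tested. Of 25 measured genes 2 rose and 3 fell, namely BOLA1 and ABCB8 at −0.72 and −0.65 and SFXN1, named after its value was seen, at −0.62, with adjusted p = 0.919 for the list. The falling members numbered 0 without FOLFIRINOX P19 and 1 without vehicle P14, vehicle P15 or both P14 libraries. Under the replicate block 6 rose and 7 fell. The list's median was −0.002 and its mean 0.08. Of 14 heme synthesis genes 1 rose, CPOX, from 3694 ± 244 to 5998 ± 249, and 1 fell (list adjusted p = 0.397), with 3 members lower under the replicate block and 0 without both P14 libraries.

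GPX4, the peroxidase that reduces membrane lipid peroxides, was 12841 ± 1294 in FOLFIRINOX and 12085 ± 3310 in vehicle (0.12 ± 0.20, 95% interval −0.32 to 0.55, adjusted p = 0.709, and 0.0112 with the replicate block and GC trends removed). The cystine importer SLC7A11 was 3814 ± 1213 against 5794 ± 2331 (−0.58 ± 0.28, adjusted p = 0.169). SLC7A11 was lower in FOLFIRINOX within each P number, and its adjusted p was 1.5e-04 with the replicate block and 0.0144 with the GC trend removed. AIFM2, the ferroptosis suppressor FSP1, differed by −0.40 ± 0.16 (adjusted p = 0.10, and 0.0175 with the replicate block) and DHODH by −0.25 ± 0.19 (adjusted p = 0.375). SCD, which makes monounsaturated fatty acids, fell 5.53-fold, from 181986 ± 37977 to 33036 ± 8026, and the acyltransferase MBOAT1 from 376 ± 79.7 to 47.8 ± 4.31. Of 29 measured ferroptosis-restraining genes none was called higher and 10 fell (median −0.29, adjusted p = 0.0037, and adjusted p = 0.122 with an estimated correlation). Under the block 4 rose and 14 fell, and 1 rose without FOLFIRINOX P14. This list shares SLC7A11, GCLC, GCLM, GSR, NQO1 and TXNRD1 with the NRF2 list below. It shares SC5D and DHCR7 with the cholesterol list and SLC7A11 and SLC3A2 with the integrated stress response list. The results of these lists are therefore not independent of each other.

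ACSL4, which activates polyunsaturated fatty acids and is known to promote ferroptosis, was 14065 ± 4497 against 17544 ± 5257 (−0.32 ± 0.25, adjusted p = 0.380, 0.0139 with the replicate block and 0.0491 with the GC trend removed). Of 26 ferroptosis-promoting genes 4 rose and 4 fell (adjusted p = 0.919), and 5 rose and 8 fell with the replicate block. SAT1, a polyamine acetyltransferase, rose from 5236 ± 697 to 19350.1 ± 3002 and GLS2, a glutaminase, from 3.80 ± 4.91 to 89.1 ± 21.2. Both are known p53 targets. CHAC1, a glutathione-degrading enzyme, fell by 1.23 and NOX4, an oxidase, by 1.21 on the log2 scale. Without both P14 libraries CHAC1 was not called (adjusted p = 0.105). The list's median was −0.11, its mean 0.26 and its camera direction down. ALOX5 on this list had no vehicle read and was at least 6.16-fold higher, and the median with ALOX5 at that bound was also −0.11.

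Of 23 cholesterol synthesis genes 18 fell and none was called higher (median −1.08, adjusted p = 1.7e-09, and adjusted p = 0.223 with an estimated correlation), with MVD down from 3266 ± 140 to 1033 ± 271 and INSIG1 from 47385 ± 6296 to 15136 ± 4972. Of 29 NRF2 target genes 2 rose and 13 fell (median −0.58, adjusted p = 4.3e-04, and adjusted p = 0.223 with an estimated correlation). PIR and CBR3 had log2 differences of −2.18 and −1.96, while AKR1B10 rose 10.9-fold to 455 ± 90.8 and EPHX1 1.59-fold, the last not called without FOLFIRINOX P15 (adjusted p = 0.0684, with 1 member then higher). Of 26 integrated stress response genes 4 rose and 14 fell (median −0.58, adjusted p = 4.0e-04, and adjusted p = 0.250 with an estimated correlation). The serine synthesis enzyme PHGDH fell from 6236 ± 792 to 1188 ± 208 and PCK2 from 2639 ± 564 to 609 ± 31.6, while SESN2, which is also on the p53 list, and ATF3 rose 2.59-fold and 1.65-fold. Without FOLFIRINOX P19, 2 of these genes were called higher.

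Of 30 lysosome genes 6 rose and 2 fell (adjusted p = 0.209), and 13 rose and 6 fell with the replicate block. FUCA1, a fucosidase, rose from 1391 ± 125 to 6618 ± 1000.1. GLB1, the gene of the β-galactosidase used as a senescence stain, was 3783 ± 464 against 5366 ± 556 (−0.51 ± 0.16, adjusted p = 0.0460), a call lost when any library but vehicle P19 was left out (adjusted p 0.0539 to 0.153) and with common-total scaling (0.132). The falling lysosome genes numbered 0 without FOLFIRINOX P15 or P19 and 1 without FOLFIRINOX P14, vehicle P14 or vehicle P15. Of 28 autophagy genes 6 rose and 2 fell (adjusted p = 0.195), 11 and 4 with the replicate block, and 1 fell without FOLFIRINOX P14, FOLFIRINOX P19, vehicle P14 or vehicle P15. Of 13 mitochondrially encoded mRNAs 3 rose and none was called lower (adjusted p = 0.137), 5 with the replicate block, beside the higher mitochondrial ribosomal RNA share given above. Of 35 nuclear respiratory chain genes 2 fell (adjusted p = 0.0555). With the replicate block 13 fell and 1 rose, and the list passed (camera adjusted p = 0.0317). It had adjusted p = 0.697 with an estimated correlation and 0.554 with that and the block. With an estimated correlation and the block even the mitosis list had adjusted p = 0.387, so the 0.554 decides nothing. Without vehicle P19 5 respiratory chain genes fell, and without FOLFIRINOX P14, FOLFIRINOX P19, vehicle P14 or vehicle P15 1 fell. At the preset correlation the respiratory chain list passed when FOLFIRINOX P14, vehicle P15 or vehicle P19 was left out (adjusted p = 0.0023, 0.0121 and 0.0169). It did not pass when FOLFIRINOX P15, FOLFIRINOX P19 or vehicle P14 was left out (0.172, 0.282 and 0.414).

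Of 28 ribosome biogenesis genes 3 fell (adjusted p = 0.506), and 3 rose and 6 fell with the replicate block. Without vehicle P19 2 ribosome biogenesis genes rose, and without any other single library 1 fell. Of 13 BCL2 family genes 5 rose and 1 fell (adjusted p = 0.216), and 3 rose without FOLFIRINOX P19. Under the block 6 rose and 2 fell. BBC3, a proapoptotic p53 target, rose 4.77-fold and BCL2, an antiapoptotic gene, fell from 237 ± 70.7 to 48.6 ± 9.74. Of 21 drug target and drug handling genes 3 rose and 7 fell (adjusted p = 0.0885), 5 and 11 with the replicate block, and 3 fell without FOLFIRINOX P19 or without both P14 libraries. TYMS, the enzyme that 5-fluorouracil inhibits, differed by −0.13, while TK1, the thymidine salvage kinase, fell 48.6-fold. TYMS was chosen here after its value was seen.

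Of 15 mesenchymal and progenitor markers 7 fell and none was called higher (median −0.55, adjusted p = 0.0034, and adjusted p = 0.306 with an estimated correlation), and the number that fell was 4 without vehicle P14 or vehicle P15 and 3 without both P14 libraries. NES fell from 19020 ± 3612 to 5846 ± 183 and COL1A1 from 496766 ± 148408 to 235090 ± 45249, the latter not called without both P14 libraries (adjusted p = 0.0891). Of 8 measured ductal epithelial markers SOX9 and KRT18 fell (list adjusted p = 0.178), and 4 fell with the replicate block. KRT18 was not called when any library but vehicle P19 was left out (adjusted p 0.0831 to 0.179). No acinar marker and 1 endocrine marker, ISL1, passed the expression filter. Of 4 immune markers CSF1R fell from 89.0 ± 31.2 to 14.2 ± 4.83, and of 3 endothelial markers ROBO4 fell from 887 ± 135 to 231 ± 33.4. Another immune marker, CD14, was called higher with the replicate block (block adjusted p = 0.0069) and 1 immune marker was higher without vehicle P19.

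In coordinates of GRCh38 (GENCODE 29, whole-gene ranges), CDKN1A lies on chromosome 6 from 36676460 to 36687339 on the plus strand, and H4C8 on the same chromosome from 26277609 to 26285638 on the minus strand. MKI67 (chromosome 10, 128096659 to 128126385), SLC40A1 (chromosome 2, 189560579 to 189583758), FDXR (chromosome 17, 74862497 to 74873031) and SLC7A11 (chromosome 4, 138164097 to 138242349) are on the minus strand. GPX4 (chromosome 19, 1103926 to 1106791), SCD (chromosome 10, 100347124 to 100364834) and CXCL8 (chromosome 4, 73740506 to 73743716) are on the plus strand.

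Adjusted over the list alone, the counts of higher and lower members were those over all genes for the p53, mitosis, replication, histone, interferon, mitochondrial iron, heme, lysosome, mitochondrially encoded, BCL2 and ductal lists. Adjusted over the list alone, 1 recombination and 1 ferroptosis-restraining gene were higher, 3 iron-handling, 5 ferroptosis-promoting, 7 autophagy and 4 drug-related genes were higher, and 17 secretory, 14 NRF2, 19 cholesterol, 15 stress response, 10 drug-related and 8 mesenchymal genes were lower. The lists of respiratory chain and ribosome biogenesis genes had 1 lower member each by that adjustment. Of 24 lists tested 11 passed with a preset correlation, and 0 passed with an estimated correlation. With fry, which asks only whether a list's own genes move 1 way, 16 passed. The authors' deposited table listed 2208 genes higher and 2300 lower at its own adjusted p under 0.05, and 4095 of its 4508 genes were also called here in the same direction.

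Counts of calls depended on the design and the libraries. With the replicate block on P number, 3995 genes were higher and 3918 lower, and every call of the unpaired fit was kept. Without FOLFIRINOX P19 the genes called higher numbered 1318, and without both P14 libraries 1162 were higher and 1368 lower. When libraries were scaled to a common total, the median log2 difference of all genes moved from 0.02 to 0.13, and 2684 genes were higher and 1699 lower, so that 61.2% of calls were higher against 48.3%.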

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

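Counts of called genes stayed within 1.5 times of the reported ones under every alternative except those given here, and no named gene called in both fits changed direction. Leaving out both P14 libraries, the replicate block on P number, edgeR on reads divided by 2 and the GC removals were chosen after seeing the data. The replicate block called 3995 genes higher and 3918 lower, and with the GC trend also removed 4232 and 4734. Without both P14 libraries 1162 were higher and 1368 lower, a fit with fewer libraries. Leaving out single libraries gave 1318 (without FOLFIRINOX P19) to 2218 genes higher. The cause was not tested.

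With an estimated correlation no list passed, not even the mitosis list, in which all 29 measured genes fell. Failing this test therefore says little about a list. The adjusted p was 0.0575 for p53, mitosis and replication, 0.122 for recombination and ferroptosis-restraining genes, 0.223 for NRF2 and cholesterol, 0.250 for stress response, 0.254 for histones, 0.306 for mesenchymal markers and 0.325 for secretory genes. With fry, the lists of iron handling (adjusted p = 0.00715), autophagy (0.00382), BCL2 family (0.00734), drug handling (5.9e-04) and ductal markers (0.0374) passed as well. The list of nuclear respiratory chain genes (adjusted p = 0.0555 in the reported fit) passed with no filter (0.00821), with the replicate block (0.0317), with the GC trend removed (0.0413) and with both (0.0245), and ranged from 0.00233 to 0.414 without single libraries, with adjusted p = 0.697 at an estimated correlation. With the GC trend removed the lysosome list passed (0.0413), and with quantile scaling the mitochondrially encoded list (0.00396). The cause was not tested.

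Over 105 named genes tested and their alternatives, 84 comparisons lost a call, 21 gained one and 2100 did neither. Genes most often losing a call were GLB1, KRT18, ABCB8, CYC1, BOLA1 and MYC. The planned block on the labels' replicate numbers was not run, because the columns carry none. Among the lists tested and the genes the rule names that are reported here, the block on P number changed no other call, while counts of called list members also moved, by 1.5 times or less where not given. Sign changes of values called in neither fit were not counted. In data simulated at this depth, number of libraries and spread, 2 of 67 changes of 1.5-fold and 33 of 67 of 2-fold were recovered, and depth alone was not varied.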

Other observations

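The lists and tests of the first 2 paragraphs were chosen after the reported values had been seen. So were the lists and tests of explanations for the histone and secretory genes, the GC analysis and the test of genes over 200 kb. Of 27 listed genes of keratinocytes and desmosomes, the junctions of stratified epithelia, 15 were measured, of which 12 rose and 1 fell. The list had a camera adjusted p of 0.199 with an estimated correlation. Some members, among them DSG3, PPL, ABCA12, NECTIN4 and KRT17, would not have passed the filter without the FOLFIRINOX libraries. Their vehicle means were 0, 1.33, 2.76, 6.15 and 9.83. The list was written after DSG3 and CLCA2 had been seen among the largest rises, and without these 2 genes 10 of 13 rose and 1 fell (median log2 difference 1.39), so its direction is not independent evidence. NECTIN4 rose from 6.15 ± 3.87 to 332 ± 74.8 normalized reads (SD, n = 3), KRT17 from 9.83 ± 8.67 to 272 ± 61.5 and DSP, desmoplakin, from 16529 ± 3376 to 47098 ± 11603. KRT15 fell, from 71.1 ± 7.34 to 23.0 ± 13.1 and was the list's only lower member, of which 0 remained called without vehicle P14 or both P14 libraries. Of 21 actin cytoskeleton genes 8 fell and none was called higher (median −0.35, adjusted p = 0.0065, and adjusted p = 0.831 with an estimated correlation), with ACTG1 down from 406620.5 ± 76415 to 187403 ± 16916. Under the replicate block 13 fell and 1 rose, and without both P14 libraries 4 fell and without vehicle P19 1 rose.

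Of 24 extracellular matrix genes 3 rose and 9 fell (median −0.47, camera adjusted p = 0.033, and adjusted p = 0.834 with an estimated correlation). COL1A1, COL1A2, COL3A1 and FN1 are also on the list of mesenchymal and progenitor markers, and all of them but FN1 were called lower. The fall of the matrix list is therefore not separate from that of the mesenchymal list. Tenascin C, TNC, fell from 3013 ± 1115 to 200 ± 45.8 and LOXL2 from 64010 ± 13497 to 23335 ± 2615, while MFAP5 rose from 88.7 ± 21.8 to 854 ± 200 and THBS1 from 132716 ± 11448 to 260318 ± 28466. The falling genes numbered 5 without vehicle P14 or vehicle P15 and 4 without both P14 libraries, 13 without vehicle P19 and 14 with the replicate block. Among 3084 long noncoding RNAs tested, 518 of 625 called were higher and 107 lower in FOLFIRINOX. Beside this, genes with reads numbered 25846 to 26126 in the FOLFIRINOX libraries against 23869 to 24171 in vehicle, and protein-coding genes took 95.8% to 97.4% of reads against 98.0% to 98.4%. The medians of the desmosome, actin and matrix lists kept their signs under each scaling alternative.

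The rise of replication-dependent histone RNA was seen in each library pair, with list medians of 1.76, 2.47 and 1.86 for P14, P15 and P19. The list median stayed at 2.14 or more under the other scalings, so the choice among these scalings was not the whole source. These scalings put the median of all genes only between −0.02 and 0.13, so a larger shift common to all genes was not tested. The 137 other single-exon protein-coding genes under 3000 bases had a median of 0.056 (95% interval −0.08 to 0.17). This argues against a general preference for intronless transcripts under 3000 bases as the whole source. These genes were not matched to histone mRNAs in length, so a preference for the shortest transcripts alone was not tested. More RNA without a poly(A) tail carried over into the FOLFIRINOX libraries cannot be told apart from more histone RNA, because only 5 other such nuclear RNAs were measured, with a median of 0.20 (−0.52 to 1.22), from RN7SL1, the most abundant, at −0.52 to SCARNA7 at 1.22, which was called with the replicate block only (block adjusted p = 0.0453). The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 were higher by 1.08 and 1.19. Of 12 mitochondrial transfer RNAs 6 were called higher (median 1.25). Of 13 mitochondrially encoded mRNAs 3 were called higher as well (median 0.14). A rise of mitochondrial RNA in general cannot be told apart from carry-over, so these values are not evidence of carry-over by themselves. P14, with the highest mitochondrial ribosomal RNA share in FOLFIRINOX (2.74% against 0.864% in vehicle), had the lowest histone median. A treatment effect on histone RNA, such as polyadenylation of histone mRNAs in arrested cells, may also apply and was not tested.

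Of 31 secretory genes 15 fell, among them CXCL8 and IL6, and 7 rose, among them IGFBP3 and AREG (3.45 and 1.77), with adjusted p = 0.325 at an estimated correlation and list medians of −0.77, −0.69 and −0.83 in the pairs. The list median stayed at −0.72 or below under the other scalings, so the choice among these scalings was not its whole source. These scalings put the median of all genes only between −0.02 and 0.13, so a larger shift common to all genes was not tested. Lower activity of NF-kB may contribute, but 29 of its targets outside the list had a median of −0.22 (−0.38 to 0.03) with 3 higher and 7 lower (5 and 8 with the replicate block), which leaves this open, and −0.06 with 2 higher and 3 lower without both P14 libraries, −0.11 with common-total and −0.11 with quantile scaling. Lower activity of YAP and TEAD also stays open, with a median of 0.10 (−0.27 to 0.44) over 23 targets, of which 6 were higher, such as CCN2 at 1.29, and 2 lower, AXL at −0.88 and CRIM1 at −0.76 (8 and 7 with the replicate block), and medians of 0.03 without both P14 libraries and 0.06 to 0.21 under the other scalings. A later onset of the secretory response than day 4 is a biological explanation that this single time point does not test.

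Across 13008 protein-coding genes, which are not independent replicates, the log2 difference fell with GC content (Spearman rho −0.23), from a median of 0.18 in the 3252 genes lowest in GC to −0.20 in the 3252 highest. The trend was −0.41 in P14, −0.15 in P15 and −0.03 in P19. Correlations of library deviations with GC content spread within a group by 2.69 times the difference of group means, part of it shared within pairs, and their within-pair differences, −0.67, −0.17 and −0.01, spread by 2.37 times their mean. With 3 pairs, all negative, GC bias between libraries unrelated to treatment cannot be told apart from a treatment effect. It was not carried by the genes of lists called lower (rho −0.23 without them) nor by gene and exonic length (partial rho −0.23), and with each library's GC trend removed 1952 of 2047 higher and 2165 of 2191 lower calls were kept.

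Platinum and topoisomerase lesions block RNA polymerase, so longer genes were tested for a larger fall. Over all 13008 genes the rank correlation with genomic span was 0.037 (0.11, −0.03 and 0.01 in P14, P15 and P19), against a steady fall with length. Given exonic length and GC content the partial rho was −0.063 (95% interval −0.08 to −0.05), within 0.1 of 0 like the value without these, so it decides nothing about them. The classes did not follow a line, with medians of −0.13 in 2375 genes under 10 kb, 0.05 in 2317 genes of 50 to 100 kb and −0.15 in 1067 genes over 200 kb, of which 22.2% were called lower and 11.5% higher. With the GC trend removed, genes over 200 kb lay below the other protein-coding genes (difference of medians −0.18, −0.22 to −0.13, and −0.20, −0.21 and −0.12 in P14, P15 and P19), which argues against the GC trend as the whole source. Because this class was picked after its median had been seen in the same libraries, the test cannot show a treatment effect on the longest genes, which stays open.

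Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many genes as observed (2047 higher, 2191 lower, 1212 and 1046 at least 2-fold), and the highest other split gave 0 in each with limma. At an unadjusted p under 0.05 the real split gave 6508 genes and the others 51 to 1667. For gene lists the real split called 11 and the highest other 8, and again 1 split of 10 gave as many. The 3 other splits that also part all P pairs called 0 genes and 8 lists each. Because 10 splits cannot give a share under 0.05, they say no more than these values. Camera with a preset correlation called several lists in most of the other splits. Every other split mixes the treatments in both of its groups. Part of the treatment difference therefore stays between the groups, and the rest adds to the spread within them. The 0 genes and the lists called there are thus not rates of false calls.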
